A study of Mus musculus with 10 samples.

How the data were processed

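The deposited files held raw UMI counts per gene and barcode, as the authors made them, for 10 libraries of RM-1 tumors from male C57BL/6 mice. Per the labels tumors were dissociated for 20 to 30 min, passed through a 70 µm strainer and run on a droplet system that reads 3' ends. The submitters' processing notes name STAR 2.7.10a, Subread with featureCounts 2.0.3, SAMtools 1.16.1 and Seurat, with the mouse genome build GRCm38. All values here were computed from the deposited counts alone. Of 32285 genes in the feature tables, 32235 IDs (99.85%) were found in GENCODE release M21, 31502 of them with the same symbol, and gene positions were taken from it. Library totals ran from 95656998 UMIs (orthotopic IRE 1) to 192001496 (orthotopic sham 2).

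Barcodes with at least 500 UMIs, at least 200 genes and under 20% mitochondrial counts were taken as cells. Scrublet scores (in scanpy 1.11.5, expected rate 0.08) were used to remove the top 0.8% of cells per 1000 barcodes of a library, which was 6.85 to 10.34% per library. That rank rule was fixed beforehand, and the threshold Scrublet set by itself marked under 0.5% in 8 of 10 libraries. From 7912 to 11505 cells per library were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbors and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 0) gave 28 clusters without integration. Further versions were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.

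Clusters were named from fixed marker genes among their leading genes, and 4 clusters stayed unnamed. Leading genes were at first ranked against all other clusters and then against clusters outside the same branch, a change made after clusters 6 and 14 would have failed naming. Cluster 14 had few UMIs, and both clusters were left out in an alternative. T cell-like cells were clustered again to name subtypes. As another alternative each cell was assigned by marker scores: 2 scoring rules were tried, and the mean of log-normalized values was kept over z-scores after the class sizes had been seen (77.37% and 47.64% of 94345 cells in the same class as by clusters).

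Counts were summed per library and class. The 4 classes fixed beforehand (tumor-like, mononuclear phagocyte-like, T cell-like and neutrophil-like), each with at least 20 cells in every library, were tested with edgeR 4.0.16 (quasi-likelihood, TMM normalization, filterByExpr) in a model with 1 mean per group, and calls needed a Benjamini-Hochberg adjusted p under 0.05 over the genes of a class and comparison. The 5 comparisons were the IRE effect at each site, their mean over both sites, their difference, and the site effect in sham tumors. All effects are log2 fold changes with the SE of the fit. Group means are given in CPM with the SD between libraries. Fold changes against 0 counts are bounds with a floor of 3 counts, and for 1 to 3 counts a 95% Poisson interval is given. DESeq2 1.42.0 was the second test.

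The 25 gene lists covered interferon (type I, gamma), antigen presentation (MHC class I, class II), T cell states (cytotoxicity, exhaustion, naive and memory, regulatory), macrophage states (lipid-laden and efferocytic, complement and tissue-resident, tissue repair and immunosuppressive), neutrophil states (mature circulating, suppressive), inflammatory cytokines, inflammasome and lytic death, immediate early and dissociation stress, integrated and ER stress, oxidative stress and iron handling, p53, hypoxia and glycolysis, oxidative phosphorylation, proliferation, extracellular matrix and wound repair, epithelial-mesenchymal transition, and androgen response. They were tested with camera in limma 3.58.1 at its preset correlation of 0.01 where at least 5 genes were measured, with an estimated correlation and with fry as alternatives. Called members are counted over all genes and adjusted over the list alone. Shares of kept cells were compared by exact two-sided permutation within sites (120 assignments over both sites, 20 under the skin, 6 in the prostate), adjusted over 11 classes, and with limma on logit shares as an alternative.

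Genes were named by a fixed rule: those with the smallest p among calls with a log2 fold change of at least 1 in size, up to 6 in each direction over both sites and between sites, 4 at each site and 3 for the difference, up to 4 list members, and 20 genes always named. Unnamed gene models, mitochondrial, ribosomal, hemoglobin and receptor variable genes, markers of another class, and genes under 0.1 of their level in the highest class were passed over, except list members and the 20 genes. For those under 0.1 of their level in another class (among them Hmox1, Myc and Cd274 in tumor-like, Prf1, Dusp1 and Fos in T cell-like, Cd74 in neutrophil-like cells) RNA of other cells was not separated. Results of 2 single genes picked by this rule are not reported here. The comparisons, tests, lists, markers, naming rule and the first set of alternatives were chosen before the data were examined. Alternatives were DESeq2 and its size factors, no low-count filter, the replicate number as a block, doublets kept, a stricter cell filter (at least 500 genes, under 10% mitochondrial), marker-score classes, genes of free RNA left out and each library left out in turn. Chosen after seeing the data were 8 more, among them z-scored classes, clusters 6 and 14 left out, clusters 4 and 16 of the phagocyte-like class each alone, T sub-clusters 10 and 11 left out, the share difference between sites and a wider family of T cell sub-clusters. The sizes of T sub-clusters per group and the grouping of splits by orthotopic labels were also tabulated after the results were seen. The blocked counts were printed together with the others before the pairing check was read, and the decision followed a rule fixed earlier.

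On simulated counts with 200 planted changes, edgeR found 78.8% of 4-fold and 41.8% of 2-fold changes in tumor-like cells for the orthotopic effect, 87.9% and 34.3% in phagocyte-like, 84.8% and 31.3% in T cell-like and 68.2% and 13.4% in neutrophil-like cells. Between 0 and 11 unchanged genes were called per run. Batch, day and surgeon are not in the labels and could not be modeled.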

Results

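The deposited counts came from single-cell 3' RNA sequencing of 10 tumors grown from the mouse prostate cancer line RM-1 in male C57BL/6 mice. Irreversible electroporation (IRE), a series of short high-voltage pulses that permeabilize cell membranes, was compared with sham treatment at 2 sites. Tumors under the skin (subcutaneous) numbered 3 sham and 3 IRE, and tumors in the prostate (orthotopic) numbered 2 sham and 2 IRE. Per the labels each tumor was a separate animal, treated at about 300 mm3 and harvested on day 7, the IRE tumors received 80 pulses at 2000 V/cm, and every p-value below rests on that independence. The 3 subcutaneous sham libraries held 12929, 8558 and 10274 barcodes with a median of 8122, 13432.5 and 10432.5 UMIs (unique molecular identifiers) per barcode. The 3 subcutaneous IRE libraries held 9232, 9450 and 11663 barcodes with a median of 9868, 13232 and 8795 UMIs. The orthotopic libraries held 11705 and 12599 barcodes (sham, 7473 and 13019 UMIs) and 10264 and 11529 barcodes (IRE, 8177 and 10822 UMIs).

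Of 108203 barcodes, 98081 cells were kept and grouped into 28 clusters, which were given class names from marker genes. Tumor-like cells, marked by keratin genes and by the oncofetal gene Hmga2, numbered 76874 with a median of 11633.5 UMIs. Mononuclear phagocyte-like cells numbered 9062 (2954 UMIs), neutrophil-like cells 2231 (881 UMIs) and T cell-like cells 1745 (2247 UMIs). These 4 classes, chosen before the data were examined, had at least 20 cells in every library and were tested gene by gene. Natural killer (NK) cell-like cells (610), dendritic cell-like cells (755), B lineage-like cells (449), endothelial-like cells (542), fibroblast-like cells (1675), mural-like cells (257) and normal prostate epithelium-like cells (145) were compared only by their shares. Different clusters made up the tumor-like class at the 2 sites. Clusters 0, 1, 2, 5 and 6 held most tumor-like cells of subcutaneous sham tumors (22.5 ± 1.94% in cluster 0, SD, n = 3), and clusters 3, 10, 12 and 7 those of orthotopic sham tumors (34.9 ± 4.63% in cluster 3, SD, n = 2). Among phagocyte-like cells cluster 16 made up 40.2 ± 2.73% in subcutaneous sham, 33.9 ± 11.8% in subcutaneous IRE (SD, n = 3 each), 1.78 ± 0.23% in orthotopic sham and 33.9 ± 23.6% in orthotopic IRE tumors (SD, n = 2 each), and cluster 4 made up the rest.

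The first question was whether IRE tumors held a different mix of cells. Tumor-like cells were 79.4 ± 6.88% of kept cells in subcutaneous sham, 85.2 ± 5.29% in subcutaneous IRE (SD, n = 3 each), 71.0 ± 5.15% in orthotopic sham and 77.0 ± 0.64% in orthotopic IRE tumors (SD, n = 2 each). Dendritic cell-like cells, which present antigen to T cells, were 0.869 ± 0.219% against 0.383 ± 0.229% under the skin and 1.503 ± 0.249% against 0.311 ± 0.077% in the prostate, and each IRE tumor lay below every sham tumor of its site. Phagocyte-like cells were 6.78 ± 1.20% against 4.58 ± 1.63% and 18.1 ± 4.84% against 9.57 ± 1.92%. Neutrophil-like cells were 1.31 ± 0.78% against 1.90 ± 0.574% and 2.05 ± 0.943% against 4.67 ± 1.75%. NK cell-like cells, which kill stressed cells without prior priming, were 0.551 ± 0.153% against 0.513 ± 0.217% under the skin and 1.32 ± 0.037% against 0.092 ± 0.021% in the prostate. Two-sided exact permutation tests within the sites gave p = 0.0167 for dendritic cell-like cells (adjusted p = 0.1833), p = 0.0333 for phagocyte-like cells (adjusted p = 0.1833), p = 0.05 for neutrophil-like cells (adjusted p = 0.1833), p = 0.1 for tumor-like cells (adjusted p = 0.275) and p = 0.1333 for NK cell-like cells (adjusted p = 0.2933), so none of the 11 classes was called. With limma on logit shares the NK cell-like effect over both sites was -1.38 (adjusted p = 0.00224) and the dendritic cell-like effect -1.28 (adjusted p = 0.00752). The NK cell-like effect by limma was -2.64 in the prostate (adjusted p = 0.000298) and -0.111 under the skin (adjusted p = 0.825), and the sites differed by -2.53 (adjusted p = 0.00463). The smallest p the exact test could reach was 0.0167 over both sites, 0.1 under the skin and 0.3333 in the prostate, so neither site alone could reach 0.05.

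**Figure D1:**
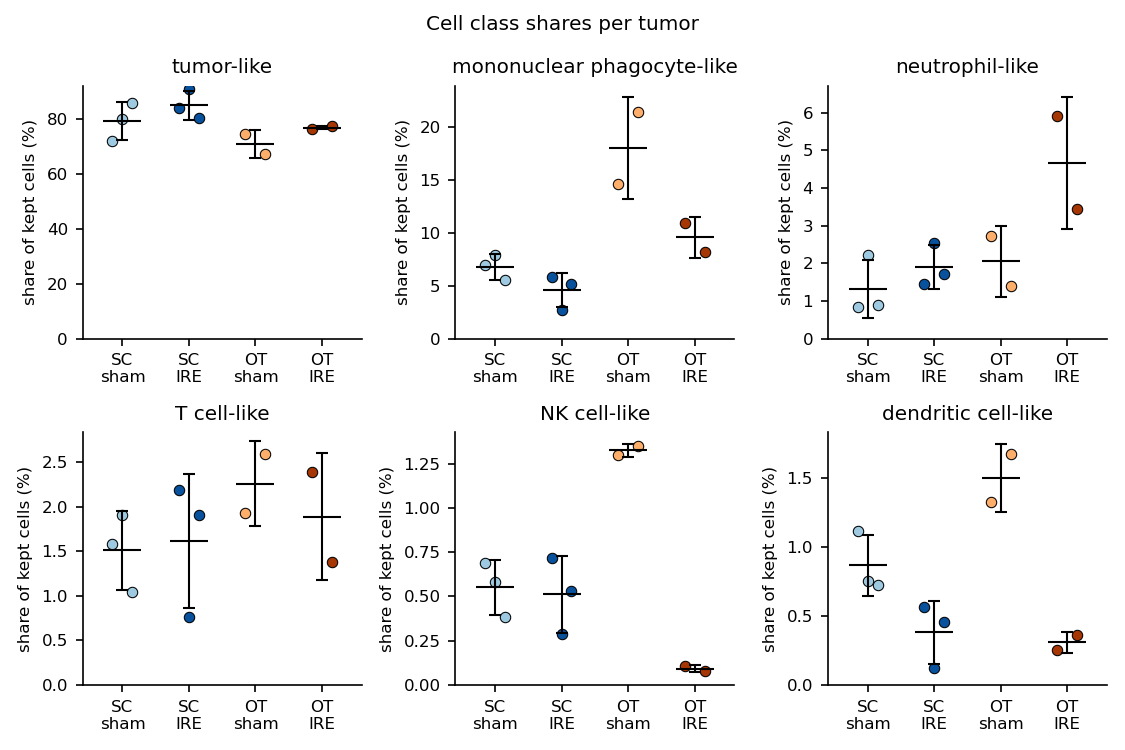
Share of kept cells (%) in 6 cell classes for the 10 tumors, by group (SC, subcutaneous, OT, orthotopic), with points for tumors and lines for the mean and SD of 3 (SC) or 2 (OT) tumors. Each IRE tumor lies below every sham tumor of its site for dendritic cell-like cells.

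T cell-like cells changed by -0.132 points over both sites (p = 0.7667, two-sided exact permutation test, n = 10 tumors) and endothelial-like cells by 0.146 points (p = 0.8). By the same exact test B lineage-like cells differed by 0.318 points (p = 0.9833), fibroblast-like cells by -0.094 (p = 0.8667), mural-like cells by 0.018 (p = 0.85) and normal prostate epithelium-like cells by 0.234 (p = 0.3333). In the prostate alone normal prostate epithelium-like cells were 0.107 ± 0.112% in sham and 0.588 ± 0.107% in IRE tumors (SD, n = 2 each). limma on logit shares called this (2.005, adjusted p = 0.0233), its difference between sites (2.99, adjusted p = 0.0094) and the dendritic cell-like effect in the prostate (-1.58, adjusted p = 0.0233). Within the T cell-like class, CD4 conventional cells, which help other immune cells, changed by -13.1 points (p = 0.05, adjusted p = 0.1, two-sided exact permutation test). Regulatory T cells, which restrain immune responses, changed by -1.90 points (p = 0.7) and gamma-delta T cells by -0.871 points (p = 0.0667, adjusted p = 0.1) in that exact test. None was called, and none alone could be. Between the sham tumors of the 2 sites phagocyte-like cells differed by 11.3 points (p = 0.1, adjusted p = 0.1571, two-sided exact permutation test), the smallest p that 3 against 2 tumors allow.

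The second question was how orthotopic and subcutaneous tumors differed without treatment (3 subcutaneous against 2 orthotopic sham tumors). In tumor-like cells Heph, the gene of the ferroxidase hephaestin that exports iron (ENSMUSG00000031209, chromosome X, 96455359 to 96574485, plus strand, GRCm38), was higher in the prostate by 5.03 ± 0.39 (log2 fold change ± SE), from 15.7 ± 5.42 to 511 ± 17.6 CPM (counts scaled to a common library total; SD, n = 3 and 2, edgeR adjusted p = 0.000116). Gstp1 (2.83 ± 0.21; a glutathione transferase), Nphs1 (2.74 ± 0.20), Lpcat4 (1.70 ± 0.10) and Plscr1 (1.43 ± 0.11; an interferon-inducible membrane protein) were higher as well. Lower in the prostate were Kcnd3 (-3.58 ± 0.26; a potassium channel), Mapt (-3.45 ± 0.24; the tau protein), Celf2 (-2.68 ± 0.20; from 108 ± 9.81 to 16.8 ± 3.79 CPM) and Nwd1 (-2.68 ± 0.13, adjusted p = 4.43e-05), as well as B4galnt2 (-2.89 ± 0.22) and Fbxo47 (-2.74 ± 0.21). Tomm6os (4.53 ± 0.32) is antisense to a coding gene, so its assignment is uncertain. edgeR called 4653 of 18107 genes in this class (2354 higher, 2299 lower in the prostate).

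Interferon and antigen-presentation genes stood higher in orthotopic sham tumor-like cells. Of the interferon-gamma response list (22 genes, median 2.83) 17 genes were higher over all genes and 20 adjusted over the list alone (camera adjusted p = 1.98e-08, adjusted p = 0.48 with an estimated correlation), among them Gbp2 (3.92 ± 0.85) and Serpina3g (3.79 ± 0.73). Of the MHC class I presentation list (16 genes, median 1.26) 13 were higher and 14 adjusted over the list alone (adjusted p = 7.82e-08, adjusted p = 0.48 with an estimated correlation). H2-T23 stood at 3.46 ± 0.56 and Psmb10 at 1.86 ± 0.29. The type I interferon response list had a median of 1.37 (24 genes, 9 higher, 14 adjusted over the list alone, adjusted p = 2.64e-05, adjusted p = 0.58 with an estimated correlation). The inflammasome and lytic death list had a median of 0.31 (17 genes, 4 higher, 5 adjusted over the list alone, adjusted p = 0.00707, adjusted p = 0.448 with an estimated correlation). B2m, the light chain of MHC class I, was higher by 0.69 ± 0.22 (adjusted p = 0.0421), Cxcl10 by 1.69 ± 0.40 (867 ± 290 against 2794 ± 11.96 CPM) and Cd274, the gene of the checkpoint ligand PD-L1, by 3.03 ± 0.67 (adjusted p = 0.011), though at 21.7 CPM against 1408 in neutrophil-like cells, so RNA of other cells was not separated. Spp1 was lower by 0.54 ± 0.14 (-0.54, adjusted p = 0.0209). H2-K1 (0.35) and Krt8 (0.15) were not called.

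In phagocyte-like cells (cluster 4 and, at 1.78% in orthotopic sham tumors, cluster 16) genes of resident macrophages were lower in the prostate. Cx3cr1, the fractalkine receptor (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879, minus strand), was lower by 3.09 (-3.09 ± 0.21, from 116 ± 20.7 to 13.3 ± 2.57 CPM, edgeR adjusted p = 3.85e-06, n = 3 and 2). Gpr183 (-2.64 ± 0.17), Ppbp (-6.37 ± 0.43; a platelet-type chemokine), Fcrls (-5.50 ± 0.48), Plcd4 (-2.71 ± 0.24), Rnase4 (-3.02 ± 0.26) and Hmox1 (-2.47 ± 0.29; heme oxygenase 1) were lower too. Plaur (1.70 ± 0.17; the urokinase receptor), Sdhd (1.57 ± 0.16), Tecpr2 (1.58 ± 0.16), Gstp1 (2.34 ± 0.24) and Heph (4.19 ± 0.30) were higher, and Hist1h2ap (4.10 ± 0.42) has near-identical paralogs, so its assignment is uncertain. The complement and tissue-resident macrophage list had a median of -1.80 (14 genes, 11 lower, 12 adjusted over the list alone, adjusted p = 4.3e-14, adjusted p = 0.348 with an estimated correlation). For the proliferation list the median was -0.89 (24 genes, 14 lower, 17 adjusted over the list alone, adjusted p = 1.66e-07, adjusted p = 0.468 with an estimated correlation), and Mki67 was lower at -1.07 ± 0.25 (adjusted p = 0.0108). In cluster 4 alone the proliferation median was -0.033 and Mki67 stood at -0.06, neither called, and Rnase4 (-1.10) was not called there either. edgeR called 2082 of 11022 genes (1007 higher, 1075 lower).

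T cell-like cells of orthotopic sham tumors had less Cd8b1, a chain of the CD8 coreceptor (-1.71 ± 0.25; 229 ± 16.7 against 67.0 ± 23.4 CPM, SD, n = 3 and 2, edgeR adjusted p = 0.000796), and less S100a16 (-2.86 ± 0.34), Il11 (-3.42 ± 0.44), Tm4sf1 (-1.98 ± 0.31), Dstn (-1.69 ± 0.25) and Btg1 (-1.68 ± 0.26). Heph (5.20 ± 0.30), Polr2l (3.42 ± 0.41), H2-T23 (1.72 ± 0.26), Eno1 (1.67 ± 0.23) and Sap18 (1.20 ± 0.21) were higher, as was Hist1h2ap (5.85 ± 0.55), whose assignment is uncertain. The epithelial-mesenchymal transition list had a median of -0.79 (12 genes, 2 lower, 6 adjusted over the list alone, adjusted p = 0.00248, adjusted p = 0.348 with an estimated correlation). Without T sub-clusters 10 and 11, which carry tumor and myeloid genes, that median was 0.096, and Tm4sf1 (-0.16), Dstn (-0.59) and S100a16 (-2.03) were not called. Foxp3 (0.53), Gzmb (0.42), Ifng (0.85), Pdcd1 (0.16), Prf1 (-0.01), Myc (0.76) and Mki67 (0.65) were not called in this class. edgeR called 304 of 7653 genes (85 higher, 219 lower).

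Neutrophil-like cells of orthotopic sham tumors carried more H2-T23 (3.14 ± 0.48; 29.8 ± 13.2 against 282 ± 38.7 CPM, SD, n = 3 and 2, edgeR adjusted p = 0.00445), Psme2 (2.60 ± 0.42), Ptgs2 (2.32 ± 0.37; the prostaglandin synthase COX-2), Mmp9 (2.00 ± 0.33) and Ly6e (1.88 ± 0.31). Hypoxia and glycolysis genes were lower, among them Hk2 (-2.82 ± 0.47), Hilpda (-2.47 ± 0.43) and Ldha (-1.83 ± 0.32), as were Hmox1 (-2.96 ± 0.44), Ccl6 (-2.09 ± 0.32) and Jun (-1.86 ± 0.32). Of the hypoxia and glycolysis list (23 genes, median -0.99) 6 were lower and 12 adjusted over the list alone (adjusted p = 3.31e-07, adjusted p = 0.468 with an estimated correlation). Il1b (0.66), Cd274 (1.26) and Vegfa (-0.18) were not called. edgeR called 242 of 3403 genes (139 higher, 103 lower).

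Counts of the site comparison depended on single libraries. In tumor-like cells they were 2645 without subcutaneous sham 2, 2670 without subcutaneous sham 3, 2401 without orthotopic sham 1, 1020 without orthotopic sham 2, 7363 without orthotopic IRE 1 and 7315 without orthotopic IRE 2. Phagocyte-like cells had 1420, 990 and 1231 without subcutaneous sham 1, 2 and 3, and 816 and 229 without orthotopic sham 1 and 2. T cell-like cells had 92, 181 and 140 without subcutaneous sham 1, 2 and 3, 491 without subcutaneous IRE 1, and 132 and 15 without orthotopic sham 1 and 2. Neutrophil-like cells had 68 and 42 without subcutaneous sham 2 and 3, 26 and 38 without orthotopic sham 1 and 2, and 494 and 490 without orthotopic IRE 1 and 2. Btg1, Dstn, Tm4sf1, Eno1, H2-T23 and Sap18 in T cell-like cells, Mki67 in phagocyte-like cells, and Hilpda in neutrophil-like cells lost the call without orthotopic sham 2. Ccl6 and Hk2 lost it without orthotopic sham 1, Jun and Ldha in neutrophil-like cells without either orthotopic sham library, and Cd274 in tumor-like cells without orthotopic sham 2. Cxcl10 lost it without subcutaneous sham 3 or either orthotopic sham library, Spp1 without any of the 5 sham libraries, and B2m without any library except orthotopic IRE 1 and 2. Site cannot be told apart from the day of handling or from any difference in library making or read processing between the sites, none of which the labels record, and this holds for Heph and Gstp1 too.

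The third question was what IRE did under the skin (3 sham against 3 IRE tumors). edgeR called 0 genes in each of the 4 classes. At unadjusted p under 0.05 it listed 1187 genes in tumor-like, 720 in phagocyte-like, 451 in T cell-like and 158 in neutrophil-like cells, and DESeq2 called 62, 4, 5 and 0. Without subcutaneous IRE 2 there was 1 call in tumor-like, 1 in phagocyte-like and 7 in T cell-like cells, and without subcutaneous IRE 1 there were 31 in T cell-like cells. In a test with planted 4-fold changes edgeR found 77.3% of them in tumor-like and 66.7% in neutrophil-like cells, and of 2-fold changes 53.7% and 13.4%.

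Several gene lists shifted by small amounts under the skin, each with 0 called genes. In tumor-like cells the immediate early and dissociation stress list, which holds rapidly induced transcription factors, had a median of -0.43 (23 genes, camera adjusted p = 2.55e-11, adjusted p = 0.401 with an estimated correlation). Nr4a1 stood at -0.65 ± 0.18 and Klf4 at -0.46 ± 0.12, neither called. The extracellular matrix and wound repair list had a median of -0.36 (22 genes, 1 lower adjusted over the list alone, adjusted p = 2.75e-06, adjusted p = 0.348 with an estimated correlation) and the epithelial-mesenchymal transition list of -0.14 (17 genes, adjusted p = 0.00581, adjusted p = 0.348 with an estimated correlation). In phagocyte-like cells the oxidative phosphorylation list had a median of -0.27 (20 genes, adjusted p = 8.65e-06, adjusted p = 0.401 with an estimated correlation). In T cell-like cells the naive and memory T cell list had a median of 1.01 (11 genes, 4 higher adjusted over the list alone, adjusted p = 1.03e-07, adjusted p = 0.421 with an estimated correlation). Satb1 stood at 1.62 ± 0.36 and was not called over all genes. The list call was lost without subcutaneous IRE 3, which held 124 of the 179 cells of T sub-cluster 5 (led by Lef1 and S1pr1). In neutrophil-like cells the hypoxia and glycolysis list had a median of -0.38 (23 genes, adjusted p = 0.000327, adjusted p = 0.735 with an estimated correlation), a call lost without subcutaneous sham 2.

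The fourth question was what IRE did in the prostate (2 sham against 2 IRE tumors). Tumor-like cells of the 2 groups lay in different clusters: cluster 8, with Areg and Sgk1 among its leading genes, held 0.933 ± 0.89% of them in sham and 28.8 ± 15.6% in IRE tumors (SD, n = 2 each). Cluster 9 held 3.13 ± 3.32% and 20.3 ± 22.4%, cluster 3 held 34.9 ± 4.63% and 14.98 ± 11.8%, and cluster 12, led by the interferon genes Rsad2 and Cxcl10, held 14.1 ± 8.32% and 3.88 ± 5.27%. Changes within these clusters were not tested. In tumor-like cells Sgk1, a kinase induced by glucocorticoids and cell stress (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903, plus strand), rose by 2.30 ± 0.24, from 107 ± 4.37 to 528 ± 82.3 CPM (SD, n = 2 each, edgeR adjusted p = 0.00943). Btg2, an antiproliferative early response gene, rose by 2.01 ± 0.22 (226 ± 33.6 to 912 ± 142 CPM), the activator protein 1 member Fosl2 by 1.11 ± 0.11 and Ipmk by 1.14 ± 0.12, all with adjusted p = 0.00943. Hmox1, which breaks down heme (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589, plus strand), rose by 2.31 ± 0.19 (8.18 ± 0.585 to 40.5 ± 4.37 CPM, adjusted p = 0.00446), at a level far under the 795 ± 69.1 CPM of phagocyte-like cells in the same tumors. Myc rose by 1.99 ± 0.38 (adjusted p = 0.0328), at 11.4 CPM over all tumors against 207 in fibroblast-like cells, and RNA of other cells was not separated for it or Hmox1. Ceacam16 (-1.28 ± 0.19), Ppp1r9a (-1.17 ± 0.18; 10.2 ± 0.039 to 4.54 ± 0.78 CPM) and Zfhx2 (-1.07 ± 0.17) fell. edgeR called 560 of 18107 genes (371 rose, 189 fell).

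By list, stress genes stood higher and interferon genes lower in tumor-like cells of orthotopic IRE tumors, with few single genes called. The immediate early and dissociation stress list had a median of 0.88 (23 genes, 5 rose, 12 adjusted over the list alone, camera adjusted p = 4.68e-12, adjusted p = 0.204 with an estimated correlation). Nr4a1 stood at 1.60 ± 0.22, Klf6 at 1.58 ± 0.24 and Klf4 at 1.11 ± 0.15. The integrated and ER stress response list had a median of 0.52 (20 genes, 6 rose, 10 adjusted over the list alone, adjusted p = 1.89e-06, adjusted p = 0.0896 with an estimated correlation). Atf4 stood at 0.91 ± 0.12 and the chaperone gene Hspa5 at 0.74 ± 0.13. For the oxidative stress and iron handling list the median was 0.53 (16 genes, 2 rose, 6 adjusted over the list alone, adjusted p = 7e-07, adjusted p = 0.126 with an estimated correlation), and for the p53 response list 0.38 (16 genes, 3 rose, 3 adjusted over the list alone, adjusted p = 0.00291, adjusted p = 0.112 with an estimated correlation). Plk2 stood at 2.27 ± 0.25. MHC class I presentation had a median of -0.85 (16 genes, 1 fell, 8 adjusted over the list alone, adjusted p = 2.91e-09, adjusted p = 0.328 with an estimated correlation), type I interferon response of -1.26 (24 genes, 0 fell at either adjustment in edgeR, adjusted p = 2.37e-08, adjusted p = 0.434 with an estimated correlation) and interferon-gamma response of -1.42 (22 genes, 1 fell at either adjustment, adjusted p = 7.01e-08, adjusted p = 0.414 with an estimated correlation). Single interferon genes such as Gbp2 (-2.05 ± 0.92) and Serpina3g (-1.64 ± 0.79) were not called. The p53 call was lost without orthotopic IRE 1. The androgen response list, of interest in a prostate tumor, had a median of 0.08 and a mean of 0.34 and was not called (10 genes, 2 rose, 4 adjusted over the list alone, adjusted p = 0.0547).

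Those tumor-like calls leaned on few libraries. The 560 calls became 91, 40 and 42 without subcutaneous sham 1, 2 and 3, 207 and 94 without subcutaneous IRE 1 and 3, 0 without either orthotopic sham library, 5009 without orthotopic IRE 1 and 848 without orthotopic IRE 2. At the count of 0 all named genes above lost the call in edgeR, while the log2 fold change of Sgk1 stayed between 2.09 and 2.44 and that of Hmox1 between 2.14 and 2.40. With all libraries 560 genes were called by edgeR and 1803 by DESeq2.

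In phagocyte-like cells (clusters 4 and 16) of orthotopic IRE tumors, Plagl1, a zinc finger regulator, rose by 3.72 ± 0.24 (3.71 ± 0.974 to 52.2 ± 6.31 CPM, SD, n = 2 each, edgeR adjusted p = 7.58e-06). Plk2 (3.09 ± 0.22; 72.8 ± 0.763 to 621 ± 3.12 CPM), Ltc4s (3.45 ± 0.26; leukotriene C4 synthase) and Hmox1 (3.27 ± 0.31; 82.9 ± 11.3 to 795 ± 69.1 CPM) rose as well, and so did Ppbp (5.95 ± 0.46) from 0.412 ± 0.195 to 31.5 ± 4.18 CPM. Spp1, which encodes osteopontin (3.05 ± 0.59), Myc (1.72 ± 0.28), the mannose receptor gene Mrc1 (1.97 ± 0.43) and the T cell attractant Cxcl10 (1.52 ± 0.36) rose. Vdr, the vitamin D receptor (ENSMUSG00000022479, chromosome 15, 97854425 to 97910630, minus strand), fell by 2.67 (-2.67 ± 0.24; 133 ± 1.61 to 20.9 ± 2.93 CPM), and Ece1 (-2.40 ± 0.22), Runx3 (-1.50 ± 0.18) and Prkcd (-1.38 ± 0.18) fell. edgeR called 1225 of 11022 genes (779 rose, 446 fell). Without orthotopic sham 1 and 2 the count was 506 and 206. Spp1 and Cxcl10 lost the call without either orthotopic sham library, and Mrc1 without orthotopic sham 1, orthotopic sham 2 or orthotopic IRE 2. In cluster 4 alone Mrc1 turned to -0.63 and Cxcl10 stood at 1.41, neither called.

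Macrophage lists stood higher in this class, in which cluster 16 held a larger part of the cells after IRE. The lipid-laden and efferocytic macrophage list, genes of cells that have taken up dead cells, had a median of 1.80 (21 genes, 15 rose, 15 adjusted over the list alone, camera adjusted p = 7.26e-18, adjusted p = 0.0896 with an estimated correlation). The cholesterol exporter Abca1 stood at 2.78 ± 0.27 and Ctsb at 1.83 ± 0.22. The inflammatory cytokines list had a median of 1.67 (21 genes, 13 rose, 15 adjusted over the list alone, adjusted p = 2.42e-16, adjusted p = 0.0896 with an estimated correlation). Ccl4 stood at 3.10 ± 0.27. For the tissue repair and immunosuppressive macrophage list the median was 2.78 (19 genes, 11 rose and 2 fell, 11 and 3 adjusted over the list alone, adjusted p = 2.91e-09, adjusted p = 0.0896 with an estimated correlation). Stab1 stood at 3.23 ± 0.29, Gas6 at 3.97 ± 0.46 and Pf4 at 4.16 ± 0.47. The complement and tissue-resident macrophage list had a median of 1.27 (14 genes, 12 rose, 13 adjusted over the list alone, adjusted p = 4.58e-12, adjusted p = 0.0946 with an estimated correlation). The hemoglobin scavenger receptor Cd163 stood at 5.93 ± 0.79. The immediate early and dissociation stress list had a median of 1.35 (23 genes, 17 rose, 21 adjusted over the list alone, adjusted p = 5.72e-20, adjusted p = 0.0932 with an estimated correlation). The suppressive neutrophil list had a median of 1.33 (17 genes, 10 rose, 12 adjusted over the list alone, adjusted p = 1.18e-12, adjusted p = 0.0896 with an estimated correlation). The mature circulating neutrophil list, markers of another class, stood higher too, with a median of 3.33 (11 genes, 6 rose, 8 adjusted over the list alone, adjusted p = 4.76e-07, adjusted p = 0.0896 with an estimated correlation), 1.23 without orthotopic IRE 2 and 2.05 without orthotopic sham 1. In cluster 4 alone its median was 4.33. Cxcl2 and Il1b averaged 31357 and 10782 CPM in neutrophil-like against 2423 and 2511 in phagocyte-like cells, and RNA of neutrophils in this class was not separated from its own cytokine genes. MHC class I presentation had a median of -0.74 (16 genes, 5 fell, 10 adjusted over the list alone, adjusted p = 5.45e-05, adjusted p = 0.414 with an estimated correlation). In cluster 4 alone the medians were 1.32 for the lipid-laden, 0.147 for the tissue repair and 0.035 for the complement list.

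T cell-like cells of orthotopic IRE tumors were a different mix of sub-clusters than those of orthotopic sham tumors. Regulatory sub-clusters 4 and 9 held 82 of 495 cells in orthotopic sham and 19 of 368 in orthotopic IRE tumors, sub-cluster 1 (led by Ccl4 and Ifng) 22 and 134, and sub-cluster 2 (led by Xcl1 and Klra7) 105 and 9. The values below are for the class as a whole, and changes within its sub-clusters were not tested. Sgk1 rose by 2.41 ± 0.28 (15.8 ± 0.158 to 81.4 ± 16.3 CPM, SD, n = 2 each, edgeR adjusted p = 0.000199), Jun by 1.83 ± 0.23, Ppp1r15a by 2.22 ± 0.28 and Filip1 by 3.83 ± 0.51. Prf1, the gene of the pore-forming protein perforin, rose by 1.94 ± 0.47 (29.4 ± 30.4 to 122 ± 78.7 CPM, adjusted p = 0.0465). Il2ra, the high-affinity interleukin 2 receptor chain of regulatory T cells (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193, plus strand), fell by 2.23 (-2.23 ± 0.39; 265 ± 82.2 to 51.7 ± 23.6 CPM, adjusted p = 0.00484), and Ifi27l2a (-2.03 ± 0.28; 942 ± 104 to 221 ± 101 CPM), Ccl2 (-1.66 ± 0.25) and Ifitm3 (-1.35 ± 0.24) fell. Without T sub-clusters 10 and 11 Ccl2 stood at -1.16 and was not called. edgeR called 92 of 7653 genes (59 rose, 33 fell). The count was 158 without subcutaneous IRE 1, 33 without orthotopic sham 1, 16 without orthotopic sham 2 and 52 without orthotopic IRE 2. Prf1 lost the call without subcutaneous sham 1, subcutaneous sham 3, orthotopic sham 1 or orthotopic IRE 1, Il2ra without orthotopic sham 2, Filip1 without orthotopic IRE 1 and Ifitm3 without orthotopic sham 2 or orthotopic IRE 1.

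Among the lists in T cell-like cells the immediate early and dissociation stress list had a median of 1.18 (22 genes, 11 rose, 19 adjusted over the list alone, camera adjusted p = 3.78e-32, adjusted p = 0.0438 with an estimated correlation). Dusp1 stood at 2.12 ± 0.23 and Fos at 2.65 ± 0.33. T cell cytotoxicity had a median of 0.86 (20 genes, 5 rose, 10 rose and 1 fell adjusted over the list alone, adjusted p = 1.26e-09, adjusted p = 0.126 with an estimated correlation). Gzmk stood at 2.38 ± 0.37, Ccl4 at 2.73 ± 0.47 and Eomes at 1.65 ± 0.34. T cell exhaustion had a median of 0.68 (15 genes, 3 rose, 8 adjusted over the list alone, adjusted p = 3.47e-06, adjusted p = 0.126 with an estimated correlation). Nr4a2 stood at 1.61 ± 0.26 and the inhibitory receptor Lag3 at 1.68 ± 0.31. The regulatory T cell list had a median of -1.03 (12 genes, 3 fell, 1 rose and 7 fell adjusted over the list alone, adjusted p = 1.49e-07, adjusted p = 0.228 with an estimated correlation). Areg stood at -2.25 ± 0.47 and Ikzf2 at -1.50 ± 0.34. The naive and memory T cell list had a median of -1.36 (11 genes, 1 fell, 6 adjusted over the list alone, adjusted p = 1.89e-06, adjusted p = 0.263 with an estimated correlation).

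In neutrophil-like cells of orthotopic IRE tumors Retnlg (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496, plus strand) rose by 4.41 ± 0.48, from 292 ± 166 to 6193 ± 1132 CPM (SD, n = 2 each, edgeR adjusted p = 3.95e-05), and the collagenase gene Mmp8 by 5.07 ± 0.55 (12.2 ± 3.91 to 428 ± 126 CPM). Camp, the gene of the antimicrobial peptide cathelicidin (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617, minus strand), had 0 counts in orthotopic sham tumors and rose at least 99.1-fold. Ngp had 2 counts there (4.48 CPM, 95% interval 0.543 to 16.2) and 1240 CPM in orthotopic IRE tumors, pooled over the libraries of each group. Hmox1 rose by 3.73 ± 0.44, while Rhoh (-2.72 ± 0.36) and the short-chain fatty acid receptor gene Ffar2 (-4.03 ± 0.54; 174 ± 13.6 to 9.35 ± 9.46 CPM) fell. Bcl2a1d (-3.76 ± 0.41) and Bcl2a1a (-3.18 ± 0.39) belong to a family of near-identical survival genes, so the assignment to single members is uncertain. edgeR called 304 of 3403 genes (136 rose, 168 fell). There were 97 calls without either orthotopic sham library and 608 without orthotopic IRE 1.

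The mature circulating neutrophil list had a median of 2.42 in neutrophil-like cells (16 genes, 12 rose and 1 fell at either adjustment, the second adjusted over the list alone, camera adjusted p = 6.59e-17, adjusted p = 0.0614 with an estimated correlation). Type I interferon response had a median of -1.82 (21 genes, 11 fell, 18 adjusted over the list alone, adjusted p = 4.38e-15, adjusted p = 0.206 with an estimated correlation), with Irf7, a driver of interferon production, at -2.69 ± 0.40, Ifit3 at -3.03 ± 0.52 and Bst2 at -2.88 ± 0.52. MHC class II presentation had a median of -2.31 (6 genes, 4 fell, 5 adjusted over the list alone, adjusted p = 7.6e-07, adjusted p = 0.0624 with an estimated correlation). Cd74 stood at -2.51 ± 0.35. Interferon-gamma response had a median of -1.62 and a mean of -0.92 (15 genes, 1 rose and 4 fell, 1 and 9 adjusted over the list alone, adjusted p = 0.0004, adjusted p = 0.508 with an estimated correlation). Nos2, the inducible nitric oxide synthase gene, stood at 4.94 ± 0.90. Hypoxia and glycolysis had a median of 0.49 (23 genes, 2 rose, 4 rose and 1 fell adjusted over the list alone, adjusted p = 0.0317, adjusted p = 0.715 with an estimated correlation), a call lost without orthotopic sham 1 or orthotopic IRE 1.

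Interferon-gamma genes set the 2 orthotopic IRE tumors apart from each other. The mean log2 CPM of that list in tumor-like cells was 6.33 ± 0.49 in orthotopic sham and 4.21 ± 2.34 in orthotopic IRE tumors (SD, n = 2 each). In tumor-like cells the medians without orthotopic IRE 2 and without orthotopic IRE 1 were -0.632 and -3.95 for interferon-gamma (-1.42 with all), -0.565 and -2.66 for type I interferon (-1.26 with all) and -0.502 and -1.63 for MHC class I presentation (-0.85 with all). In phagocyte-like cells the type I interferon median of -0.541 (24 genes, 2 rose and 4 fell, 4 and 6 adjusted over the list alone, camera adjusted p = 0.0285, adjusted p = 0.766 with an estimated correlation) became 0.022 without orthotopic IRE 2 and -1.42 without orthotopic IRE 1, and its call was also lost without subcutaneous IRE 1 or 2. The interferon-gamma median in phagocyte-like cells was -0.642 (21 genes, 2 rose and 1 fell, 2 and 2 adjusted over the list alone, adjusted p = 0.0216, adjusted p = 0.754 with an estimated correlation) and became -0.304 without orthotopic IRE 2 (adjusted p = 0.918). In neutrophil-like cells the type I interferon median of -1.82 became -1.13 without orthotopic IRE 2 and -3.59 without orthotopic IRE 1, and the interferon-gamma median of -1.62 became -0.792 and -3.91, with each call kept.

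**Figure D2:**
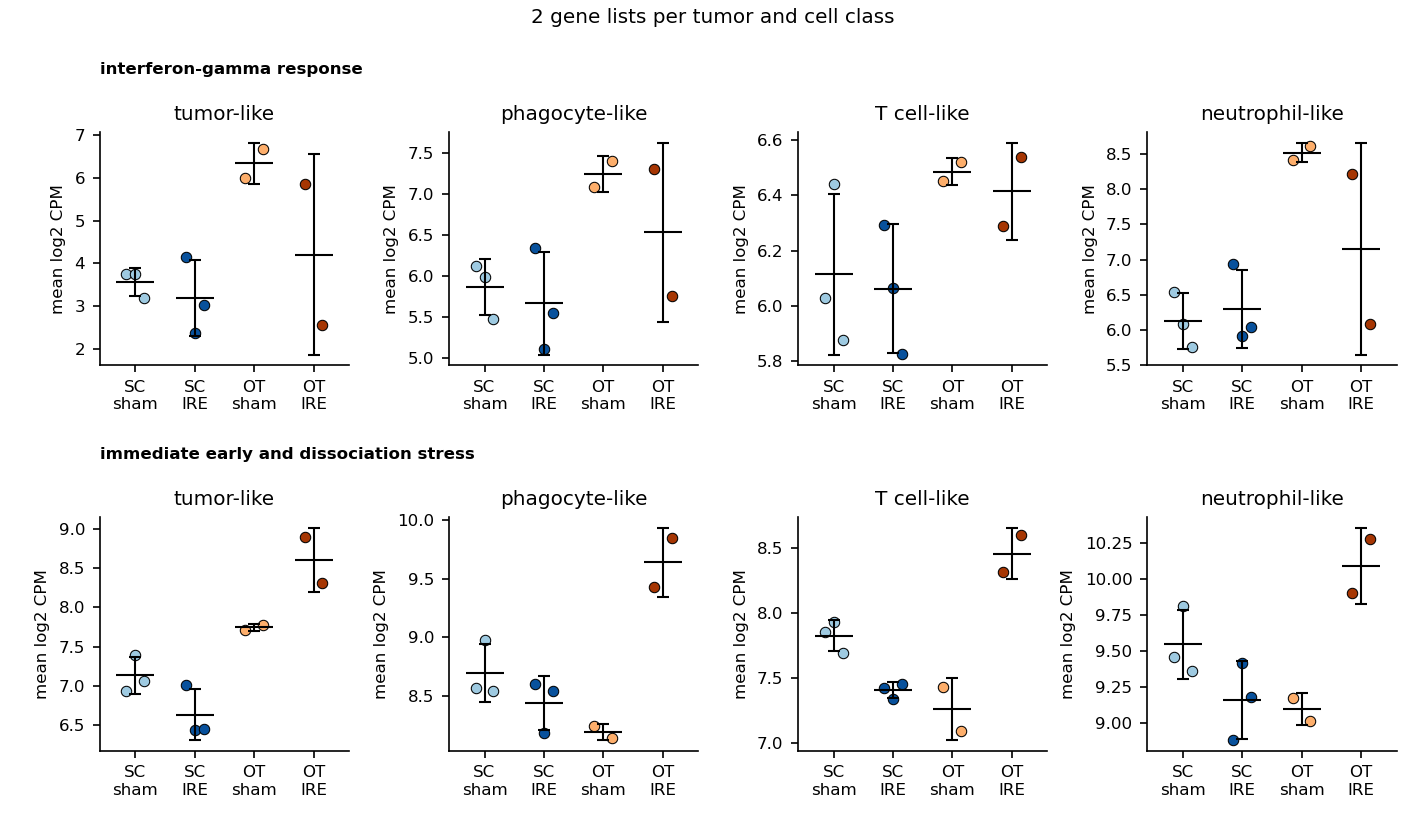
Mean log2 CPM of the interferon-gamma and the immediate early lists in 4 cell classes for the 10 tumors (SC, subcutaneous, OT, orthotopic), with points for tumors and lines for the mean and SD of each group. In tumor-like cells the interferon-gamma list averages 6.33 in orthotopic sham and 4.21 in orthotopic IRE tumors, with the 2 IRE tumors far apart.

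The fifth question was whether IRE acted differently at the 2 sites. The difference (orthotopic minus subcutaneous effect) was past the threshold in edgeR for 30 genes in tumor-like (28 positive, 2 negative), 482 in phagocyte-like (343 and 139), 46 in T cell-like (29 and 17) and 52 in neutrophil-like cells (27 and 25). In tumor-like cells it was 2.90 ± 0.30 for Sgk1, 2.44 ± 0.28 for Btg2, 1.57 ± 0.15 for Fosl2 (adjusted p = 0.00852) and 2.90 ± 0.24 for Hmox1 (adjusted p = 0.00451). In phagocyte-like cells Ltc4s (4.77 ± 0.37, adjusted p = 6.55e-05), Plagl1 (4.20 ± 0.35), Plk2 (3.11 ± 0.27), Hmox1 (3.60 ± 0.38), Vdr (-2.60 ± 0.31), Ece1 (-2.16 ± 0.29) and Sipa1l3 (-1.53 ± 0.23) differed. T cell-like cells differed in Phlda1 (2.61 ± 0.32; 312 ± 52.5 to 127 ± 32.8 CPM under the skin and 116 ± 2.50 to 309 ± 35.0 in the prostate), in Jun (2.25 ± 0.30) and in Gzmk, a granzyme of memory-type cytotoxic T cells (3.58 ± 0.50). Ifi27l2a (-2.01 ± 0.35) and Satb1 (-2.98 ± 0.55) differed in the other direction. In neutrophil-like cells Hmox1 (4.26 ± 0.55), Jun (3.42 ± 0.43), Retnlg (4.19 ± 0.58) and Irf7 (-3.36 ± 0.56) differed, as did the near-identical Bcl2a1d (-3.08 ± 0.52) and Bcl2a1a (-2.81 ± 0.49).

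Not every gene called in the prostate alone passed this test. Atf4 (0.82 ± 0.16, adjusted p = 0.0741) and Hspa5 (0.75 ± 0.17, adjusted p = 0.099) in tumor-like cells were not called for the difference by edgeR. Neither were Lag3 (1.69 ± 0.48, adjusted p = 0.149), Ikzf2 (-1.64 ± 0.43, adjusted p = 0.103) and Areg (-1.66 ± 0.58, adjusted p = 0.307) in T cell-like cells. Tap2 (-1.18 ± 0.39, adjusted p = 0.107) in phagocyte-like cells and Cd74 (-2.03 ± 0.50, adjusted p = 0.0546) and Nos2 (3.23 ± 1.37, adjusted p = 0.272) in neutrophil-like cells also stayed outside. The immediate early and dissociation stress list differed in all 4 classes, with a median of 1.23 in tumor-like (camera adjusted p = 4.96e-21, adjusted p = 0.0899 with an estimated correlation), 1.55 in phagocyte-like (adjusted p = 1.01e-23, adjusted p = 0.089 with an estimated correlation), 1.49 in T cell-like (adjusted p = 2.23e-35, adjusted p = 0.0481 with an estimated correlation) and 1.38 in neutrophil-like cells (adjusted p = 2.29e-12, adjusted p = 0.0948 with an estimated correlation). Of its genes 4, 11, 8 and 5 differed over all genes and 13, 20, 18 and 13 adjusted over the list alone. The naive and memory T cell list differed with a median of -2.44 in T cell-like cells (11 genes, 2 negative, 8 adjusted over the list alone, adjusted p = 1.31e-12, adjusted p = 0.103 with an estimated correlation).

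Single libraries moved these difference counts. In tumor-like cells the 30 calls became 4, 2, 2 and 8 without subcutaneous sham 2, subcutaneous sham 3, subcutaneous IRE 1 and subcutaneous IRE 3, 146 without subcutaneous IRE 2, 0 without either orthotopic sham library (edgeR; DESeq2 called 780 with all libraries), and 3269 and 327 without orthotopic IRE 1 and 2. Phagocyte-like cells had 184 and 235 without subcutaneous sham 2 and 3, 173 and 75 without orthotopic sham 1 and 2, and 1120 without orthotopic IRE 1. T cell-like cells had 24, 21 and 25 without subcutaneous sham 1, 2 and 3, 119 without subcutaneous IRE 1, 20 and 19 without orthotopic sham 1 and 2, and 30 without orthotopic IRE 2. Neutrophil-like cells had 28, 8 and 16 without subcutaneous sham 2, subcutaneous sham 3 and subcutaneous IRE 1, 6 and 17 without orthotopic sham 1 and 2, and 318 without orthotopic IRE 1. Sgk1 lost the call without subcutaneous sham 3, subcutaneous IRE 1 or either orthotopic sham library, Btg2 also without subcutaneous sham 2, and Fosl2 and Hmox1 in tumor-like cells without either orthotopic sham library. Satb1 lost it without orthotopic IRE 1, and Bcl2a1a and Bcl2a1d without orthotopic sham 1.

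The last question was what IRE did over both sites, with the 2 site effects given equal weight (5 sham against 5 IRE tumors). In phagocyte-like cells (clusters 4 and 16) Saa3, an acute-phase serum amyloid gene (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), rose by 3.50 ± 0.32 (edgeR adjusted p = 0.000161), from 38.8 ± 7.08 to 104 ± 38.1 CPM under the skin (SD, n = 3 each) and from 29.0 ± 15.8 to 1456 ± 903 in the prostate (SD, n = 2 each). Tnf rose by 1.58 ± 0.16 (95.8 ± 20.8 to 116 ± 21.8 and 86.0 ± 7.67 to 633 ± 170 CPM), the chemokine gene Ccl3 by 1.93 ± 0.19, Ppbp by 3.14 ± 0.26, Plk2 by 1.54 ± 0.14, Apoc2 by 1.52 ± 0.15, Hmox1 by 1.47 ± 0.19 and Spp1 by 1.74 ± 0.37. Ccl24, an eosinophil attractant of repair-type macrophages, fell by 1.63 (-1.63 ± 0.34; 2061 ± 566 to 241 ± 168 CPM in the prostate, adjusted p = 0.0178), and Ece1 (-1.32 ± 0.14), Vdr (-1.37 ± 0.15), Slc4a11 (-1.53 ± 0.29), Kbtbd11 (-1.63 ± 0.33) and Matk (-1.05 ± 0.21) fell. Under the skin alone none of these genes was called, and Hmox1 (-0.33) and Plk2 (-0.02) did not lie above 0 there, so their mean rests on the prostate. Arg1 (0.41), Mrc1 (0.82), Cxcl9 (-0.54) and H2-Ab1 (-0.76) were not called. edgeR called 440 of 11022 genes (340 rose, 100 fell). The count was 196, 278, 251 and 244 without subcutaneous sham 1, subcutaneous sham 2, subcutaneous sham 3 and subcutaneous IRE 3, 145 and 69 without orthotopic sham 1 and 2, and 737 without orthotopic IRE 1. Kbtbd11, Matk and Slc4a11 lost the call without orthotopic sham 2, Ccl24 without subcutaneous sham 3 or orthotopic sham 2, and Spp1 without subcutaneous sham 1 or either orthotopic sham library. Among the 60 ways to divide sham and IRE within the sites, the real one included, 7 gave at least 440 calls and the highest other gave 808, so chance cannot be excluded. All 7 were among the 20 that keep the 2 orthotopic groups together. A division and its mirror count once, so each of these is the real orthotopic labels with some labels of the subcutaneous tumors, the reversed ones included, and the orthotopic effect is not judged.

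Neutrophil-like cells over both sites gained Saa3 (4.09 ± 0.53, edgeR adjusted p = 0.000525), Mmp8 (2.87 ± 0.37), Retnlg (2.31 ± 0.29; 1053 ± 415 to 1225 ± 397 CPM under the skin, 292 ± 166 to 6193 ± 1132 in the prostate, SD, n = 3 and 2 per group), Wfdc21 (2.23 ± 0.31), the siderophore-binding protein gene Lcn2 (2.88 ± 0.44), Hmox1 (1.60 ± 0.27) and Jun (1.39 ± 0.21). Rhoh (-1.81 ± 0.24), Mthfsl (-1.48 ± 0.24) and Wnk1 (-1.25 ± 0.20) fell, as did Bcl2a1d (-2.22 ± 0.26), Bcl2a1a (-1.78 ± 0.25) and Bcl2a1b (-1.55 ± 0.24), whose single assignments are uncertain. Hmox1 (-0.54) and Jun (-0.32) lay below 0 under the skin and were not called there, so their mean over both sites rests on the prostate. Il1b (-0.37), Cd274 (-0.30) and Vegfa (-0.57) were not called. edgeR called 73 of 3403 genes (34 rose, 39 fell). The count was 44 and 41 without subcutaneous sham 1 and 3, 43 without subcutaneous IRE 1, 30 without either orthotopic sham library and 354 without orthotopic IRE 1. Of the 60 divisions 5, all with the orthotopic groups kept together, gave at least 73 calls and the highest other gave 121, so chance cannot be excluded.

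**Figure D3:**
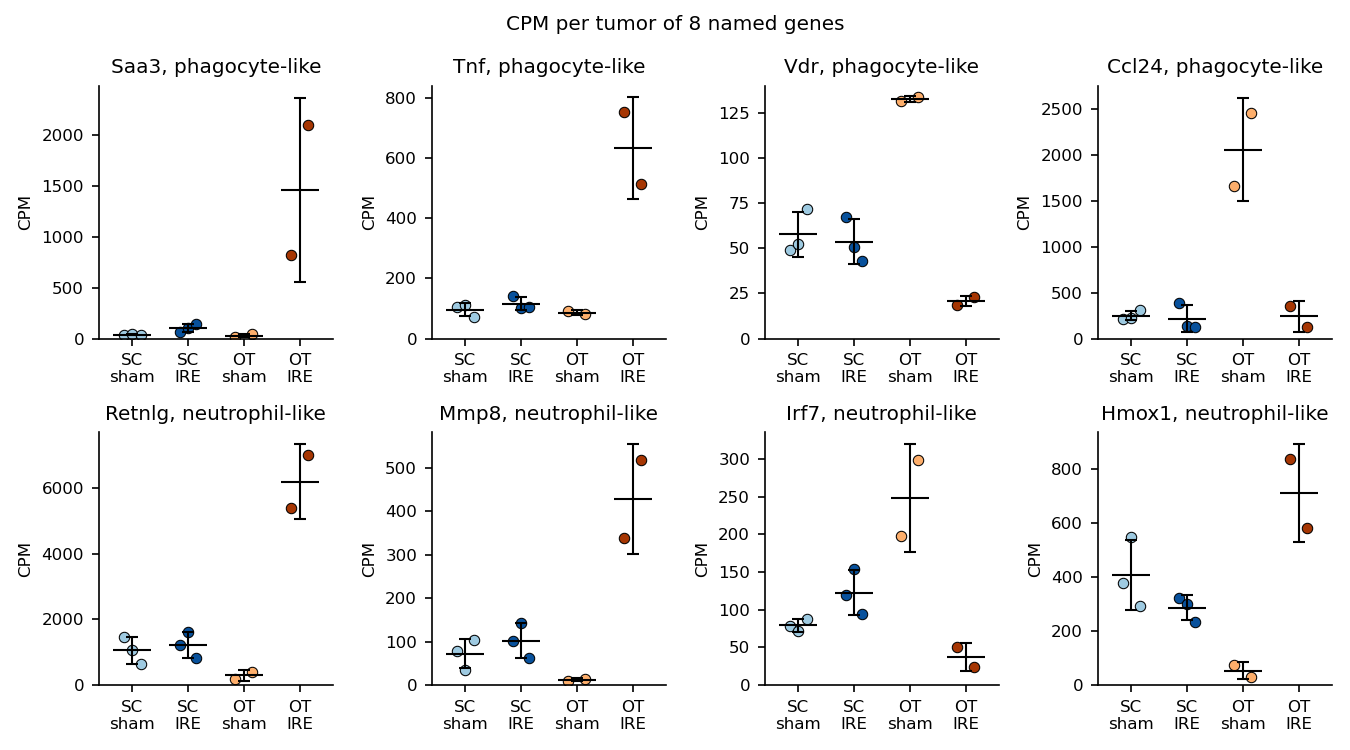
CPM of 4 genes in phagocyte-like and 4 in neutrophil-like cells for the 10 tumors (SC, subcutaneous, OT, orthotopic), with points for tumors and lines for the mean and SD of each group. Saa3 averages 1456 CPM in phagocyte-like cells of orthotopic IRE and 29.0 in those of orthotopic sham tumors.

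T cell-like cells over both sites gained Prf1 (1.72 ± 0.34; 34.9 ± 19.6 to 102 ± 17.6 CPM under the skin and 29.4 ± 30.4 to 122 ± 78.7 in the prostate, SD, n = 3 and 2 per group, edgeR adjusted p = 0.0428), the proapoptotic p53 target Bbc3 (1.41 ± 0.28), Filip1 (2.42 ± 0.37) and Dscam (1.61 ± 0.26). Ccl2 (-1.13 ± 0.16, adjusted p = 0.00862), Ifi27l2a (-1.03 ± 0.18), Prdx4 (-1.04 ± 0.20) and Areg (-1.42 ± 0.29) fell, Ifi27l2a with -0.02 under the skin, so that its mean rests on the prostate. Foxp3 (-0.44 ± 0.36), the defining factor of regulatory T cells, was not called, and neither were Gzmb (0.15 ± 0.36), Ifng (0.36 ± 0.22), Pdcd1 (0.26 ± 0.23), Myc (0.62) and Mki67 (-0.39). edgeR called 14 of 7653 genes (8 rose, 6 fell). It called none with doublets kept or with classes by z-scored marker score per cell. The count was 5, 8 and 4 without subcutaneous sham 1, 2 and 3, 29 and 36 without subcutaneous IRE 2 and 3, 2 without orthotopic sham 2 and 7 without orthotopic IRE 1. Prf1 lost the call without subcutaneous sham 1, subcutaneous sham 3, orthotopic sham 1 or orthotopic IRE 1. Filip1 and Dscam lost it without orthotopic sham 2 or orthotopic IRE 1 and Ifi27l2a without orthotopic sham 2. Areg, Prdx4 and Bbc3 each lost it without 7 of the 10 libraries. Without T sub-clusters 10 and 11 Ccl2 stood at -0.32, and Ccl2, Bbc3, Prdx4, Areg and Prf1 were not called. Of the 60 divisions 15, all with the orthotopic groups kept together, gave at least 14 calls and the highest other gave 76, so chance cannot be excluded.

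In tumor-like cells only 2 genes rose over both sites, Cyp51 (0.75 ± 0.08) and Insig1 (0.69 ± 0.08, edgeR adjusted p = 0.0326 each), both of sterol synthesis and its control. They lay outside the naming rule and were picked after the result was seen. In the prostate alone Cyp51 rose by 1.03 ± 0.12 and Insig1 by 1.01 ± 0.12 (adjusted p = 0.00943 each). B2m (-0.18), H2-K1 (-0.26), Krt8 (0.23), Spp1 (-0.02) and Cxcl10 (-0.55) were not called. The 2 calls became 0 without any of the 6 subcutaneous or the 2 orthotopic sham libraries, 3386 without orthotopic IRE 1 and 288 without orthotopic IRE 2, while DESeq2 called 913 with all libraries and edgeR at unadjusted p under 0.05 listed 3148 genes. Of the 60 divisions 5 gave at least 2 calls and the highest other gave 626, which is many times the real count. All 5 kept the orthotopic groups together, and differ only in how the subcutaneous tumors were labelled relative to them (1 is the real labels with 1 site reversed). So high a count points to a structure of the samples, whose nature was not tested.

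By list over both sites, phagocyte-like cells gained inflammatory cytokines (median 0.87, 21 genes, 9 rose, 13 adjusted over the list alone, camera adjusted p = 1.04e-18, adjusted p = 0.114 with an estimated correlation) and the lipid-laden and efferocytic macrophage list (median 0.84, 21 genes, 12 rose, 15 adjusted over the list alone, adjusted p = 1.6e-17, adjusted p = 0.115 with an estimated correlation). Neutrophil-like cells gained the mature circulating neutrophil list (median 1.07, 16 genes, 5 rose, 9 adjusted over the list alone, adjusted p = 1.28e-09, adjusted p = 0.115 with an estimated correlation) and had a median of -0.99 for type I interferon response (21 genes, 2 fell, 8 adjusted over the list alone, adjusted p = 2.13e-12, adjusted p = 0.332 with an estimated correlation). T cell-like cells had a median of -0.25 for hypoxia and glycolysis (25 genes, 1 fell, 3 adjusted over the list alone, adjusted p = 9.79e-08, adjusted p = 0.254 with an estimated correlation) and of 0.36 for T cell cytotoxicity (20 genes, 1 rose, 5 adjusted over the list alone, adjusted p = 9.75e-05, adjusted p = 0.355 with an estimated correlation). Under the skin alone the medians were 0.203 for inflammatory cytokines, 0.11 for the lipid-laden list, 0.182 for the mature neutrophil list, 0.046 for type I interferon and -0.155 for cytotoxicity in the same classes, none called, so these means rest on the prostate. The mature neutrophil list had a median of 2.08 in phagocyte-like cells as well. Across all classes and comparisons camera with its preset correlation called 199 list results, against 2 with an estimated correlation and 89 with fry, which tests for movement in one direction and does not compare with other genes.

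The orthotopic IRE effect and the site effect share the 2 orthotopic sham libraries, so their values are not independent of each other.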

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

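The tests in this part with other splits of the tumors were chosen after the result was seen, and the others were written down before their values were computed. IRE effects that differed between the 2 sites by the interaction test drew a closer look. They numbered 30 genes in tumor-like, 482 in phagocyte-like, 46 in T cell-like and 52 in neutrophil-like cells, and 12, 13, 8 and 12 gene lists (camera with its preset correlation). The named genes were Fosl2 (1.57), Sgk1 (2.90) and Btg2 (2.44) in tumor-like cells. In phagocyte-like cells they were Ltc4s (4.77), Plagl1 (4.20), Plk2 (3.11), Vdr (-2.60), Ece1 (-2.16) and Sipa1l3 (-1.53). T cell-like cells differed in Phlda1 (2.61), Jun (2.25), Gzmk (3.58), Ifi27l2a (-2.01) and Satb1 (-2.98), and neutrophil-like cells in Hmox1 (4.26), Jun (3.42), Retnlg (4.19), Irf7 (-3.36), Bcl2a1d (-3.08) and Bcl2a1a (-2.81). No group had 4 or more tumors, so no single tumor was tested for lying apart from its group.

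Interferon lists were lower in orthotopic IRE than in orthotopic sham tumors. If 1 orthotopic library were the cause, leaving it out would shrink the median of a list by more than 0.5 of its size or turn its sign. The lowest ratio was -0.041, for type I interferon in phagocyte-like cells without orthotopic IRE 2, so the pattern may rest on that library, in which both lists were lowest of the 4 orthotopic libraries in these 3 classes. Thinning every library to the smallest total of its class left at least 0.915 of each median. It keeps expected proportions, so depth is not judged. A loss of interferon signaling by treatment remains possible and would need more orthotopic tumors.

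Immediate early genes were higher in orthotopic IRE tumors in all 4 classes. The handling of single tumors, such as longer dissociation, could raise them in every class of the same tumor. The mean correlation between classes of the deviations from the group means was 0.179 (p = 0.152, one-sided permutation within groups), which does not decide between handling and treatment. A batch of orthotopic IRE tumors handled together would escape this test, because it compares tumors within groups only.

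Macrophage lists were higher in phagocyte-like cells of orthotopic IRE tumors, where cluster 16 was larger than in orthotopic sham tumors. For the lipid-laden and efferocytic macrophage list cluster 4 alone kept 0.733 of the median and cluster 16 alone 0.639. The share of cluster 16 is thus not the whole cause, but the mix within clusters is open. In cluster 4 the ratio was 0.028 for the complement and tissue-resident and 0.053 for the tissue repair and immunosuppressive macrophage list. A larger share of cluster 16 would give these. For inflammatory cytokines the ratio was 1.012 in cluster 4 and 0.298 in cluster 16. In cluster 4 the mature circulating neutrophil list also stood higher, so neutrophils or their RNA may add to these lists, which stays open. This reading follows the bound set beforehand, after a looser one, tried once the values were seen, was dropped. The clusters were made partly from these same genes, so these ratios set bounds only.

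Of the 60 splits of sham and IRE within the sites, the real one included, 5 gave at least as many calls as the real one in tumor-like (real 2, highest other 626), 7 in phagocyte-like (440, 808), 15 in T cell-like (14, 76) and 5 in neutrophil-like cells (73, 121), so chance cannot be excluded. All of these kept the 2 orthotopic groups together, as 20 of the 60 do. A split and its mirror count once, so each is the real orthotopic labels with some subcutaneous labels, the reversed ones included, and the splits judge only what the subcutaneous labels add. The 40 splits that mixed the orthotopic groups gave at most 1 call in T cell-like cells and fewer in the other classes. Under the skin alone the 10 splits are too few for a share under 0.05. The real value was 0 in all classes, so all 10 gave as many, and the highest other was 0, 0, 4 (T cell-like) and 0 (edgeR, with 1187, 720, 451 and 158 genes at unadjusted p under 0.05 and 62, 4, 5 and 0 calls by DESeq2).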

How the results depend on the processing

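The cause of the changes below was not tested. DESeq2 size factors changed no count by more than 1.5 times and no direction, though 2 list calls were lost. Counts of genes are given by class and comparison, and p-values with 1 library left in a group assume that it varies like the other groups. The 881 UMIs per neutrophil-like cell limited that class to 3403 tested genes.

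Most named genes and lists kept their direction and their side of the threshold. For named genes this held for 206 results with DESeq2 size factors, 198 with the DESeq2 test, 205 with the stricter cell filter, 188 without free-RNA genes, 183 with doublets kept, 180 with marker-score classes and 146 with z-scored classes, where 52 lost the call and 8 turned. With each library left out in turn 1828 named-gene results were kept, 202 lost the call, 14 gained it and 16 turned, while 1833 list results were kept, 141 lost the call and 4 turned. All 11 named tumor-like genes called for the orthotopic effect and all 4 called for the difference lost the call without at least 1 library. Of 13 named neutrophil-like genes called over both sites 13 kept it.

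With DESeq2 tumor-like counts were 913 over both sites (edgeR 2), 62 under the skin (0), 1803 in the prostate (560) and 780 for the difference (30). Phagocyte-like and T cell-like counts under the skin were 4 and 5 (0 each), the T cell-like site count was 164 (304) and the neutrophil-like difference 84 (52). Without the low-count filter tumor-like counts were 119 over both sites and 145 for the difference. Phagocyte-like counts were then 987 over both sites, 84 under the skin and 978 for the difference. T cell-like counts were 85, 36, 210, 155 and 591 (both sites, skin, prostate, difference, site) and neutrophil-like 119, 2 and 89 (both sites, skin, difference). The site effects of Prf1 in T cell-like (0.06) and Vegfa in neutrophil-like cells (0.02) turned positive.

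Replicate pairing stays open with so few tumors. Same-numbered tumor-like correlations were 0.407, 0.145 and -0.1 under the skin, -0.643 in the prostate and -0.552 to 0.651 across sites. With the replicate block the tumor-like count was 0 over both sites (edgeR, 2 unblocked, 913 by DESeq2), 11 in the prostate and 8 for the difference, and the site count was 1381 in phagocyte-like and 102 in neutrophil-like cells.

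With classes by marker score per cell the count was 19 over both sites in tumor-like cells and 102 for the site effect in T cell-like cells, and in neutrophil-like cells 47, 83 and 6 (both sites, prostate, difference). List medians that turned were interferon-gamma response (-0.21, T cell-like, site) and in neutrophil-like cells the integrated stress list (-0.038, skin) and the immediate early list (0.364, site). Site effects that turned were Mmp9 (-0.90) and Vegfa (0.20) in neutrophil-like and Pdcd1 (-0.09) in T cell-like cells. Over both sites the endothelial-like share changed by -0.248 points and normal prostate epithelium-like cells by -0.002.

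Classes by z-scored marker score per cell, added after seeing the data, gave 44 tumor-like calls over both sites and 1 phagocyte-like call under the skin. T cell-like counts were 0 (edgeR; 14 in the main classes), 5, 7 and 687 (both sites, prostate, difference, site) and neutrophil-like 24, 153, 12 and 132. T cell exhaustion had a median of 0.029 (T cell-like, both sites). In neutrophil-like cells the medians were -0.055 (integrated stress, skin), 0.94 and 0.641 (inflammatory cytokines, prostate and difference), 0.208 (inflammasome, difference) and 0.363 (immediate early, site). Areg in T cell-like cells came to 0.01 over both sites and Prf1 to 1.04 for the site effect. In neutrophil-like cells Mmp9 (-0.49), Jun (0.36) and Vegfa (0.23) turned for the site effect, and Cd274 (0.62), Il1b (0.63) and Vegfa (0.06) over both sites. Shares over both sites were 1.06 points for NK cell-like, -1.75 for endothelial-like and -2.89 for normal prostate epithelium-like cells.

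With free-RNA genes left out tumor-like cells had 107 calls over both sites and T cell-like cells 2 under the skin. Leaving out clusters 6 and 14 (added later) gave 10 tumor-like calls over both sites. Cluster 4 alone (added later) had 254, 563, 99 and 555 calls (both sites, prostate, difference, site). Its medians were -0.635, -0.546 and -0.033 for proliferation (prostate, difference, site) and 0.035 and -0.024 for complement (prostate, difference). There Mrc1 was -0.58, -0.63 and -0.10 (both sites, prostate, difference) and H2-Ab1 -0.02 (site). Cluster 16 alone (added later, fewer cells) had 0, 7, 0 and 37 calls (edgeR), medians of 0.082 (tissue repair, both sites), -0.29 (mature neutrophil, skin) and 0.269 (proliferation, prostate), and Matk at 0.33 over both sites.

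With doublets kept T cell-like calls were 0 over both sites (edgeR) and 123 for the site effect, neutrophil-like calls 33 for the difference and 133 for site, and Pdcd1 in T cell-like cells was -0.05 (site). Without T sub-clusters 10 and 11 (added later) T cell-like calls were 9 over both sites and 72 for site, and site values were -0.263 for interferon-gamma response, 0.096 for epithelial-mesenchymal transition and -0.17 for Pdcd1. The stricter cell filter gave 130 neutrophil-like site calls. Camera called 199 list results with its preset correlation and 2 with an estimated correlation, and fry called 89. limma on logit shares called 7 share results (exact test 0), among them over both sites NK cell-like (-1.38) and dendritic cell-like cells (-1.28). As a share of cells other than tumor-like, T cell-like cells changed by 1.75 points and fibroblast-like cells by 0.596.

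Leaving out each library in turn gave tumor-like counts of 0 to 3386 over both sites, 0 to 1 under the skin, 0 to 5009 in the prostate, 0 to 3269 for the difference and 1020 to 7363 for site. Phagocyte-like counts ran from 69 to 737, 0 to 1, 206 to 1666, 75 to 1120 and 229 to 2822 in the same order. T cell-like counts ran from 2 to 36, 0 to 31, 16 to 158, 19 to 119 and 15 to 491. Neutrophil-like counts ran from 30 to 354 over both sites, 97 to 608 in the prostate, 6 to 318 for the difference and 26 to 494 for site. At each 0 the tool was edgeR. Phagocyte-like medians in the prostate ran from -1.42 to 0.022 (type I interferon) and -1.76 to -0.304 (interferon-gamma, whose test changed direction), and T cell-like proliferation medians from -0.503 to -0.026 over both sites and -0.707 to 0.057 under the skin. Over both sites Cd274 in neutrophil-like cells ran from -1.15 to 0.08, Gzmb in T cell-like cells from -0.71 to 0.51, Pdcd1 from -0.27 to 0.44 and Spp1 in tumor-like cells from -0.12 to 0.05. For the site effect Gzmb ran from -0.22 to 0.88, Prf1 from -2.12 to 0.58 and Arg1 in phagocyte-like cells from -0.93 to 0.01. Shares over both sites ran from -0.106 to 0.534 points (B lineage-like), -0.383 to 0.12 (T cell-like), -0.028 to 0.32 (endothelial-like), -0.491 to 0.303 (fibroblast-like) and -0.034 to 0.069 (mural-like).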

Other observations

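Some genes differed between the sites alike in sham and IRE tumors and in several classes. Sdhd in phagocyte-like cells, a subunit of succinate dehydrogenase, stood at 29.2 ± 3.21 and 23.7 ± 3.55 CPM in subcutaneous sham and IRE tumors (SD, n = 3 each) and at 86.9 ± 3.33 and 84.4 ± 7.18 in orthotopic sham and IRE tumors (SD, n = 2 each). Gstp1 stood at 7.19 ± 1.06 and 11.6 ± 3.11 against 51.3 ± 2.53 and 41.1 ± 4.91 CPM in tumor-like cells and at 3.95 ± 0.224 and 3.48 ± 1.15 against 20.3 ± 2.39 and 20.8 ± 2.77 in phagocyte-like cells. Heph differed between the sites too, its IRE effect in T cell-like cells differed between them (-2.26, adjusted p = 0.0214 by edgeR), and it reached 511 ± 17.6 CPM in tumor-like, 470 ± 14.7 in T cell-like and 234 ± 41.9 in phagocyte-like cells of orthotopic sham tumors. Site goes together with any difference in library making or read processing between the sites, which no test here separates, so what the site effects of these genes stand for is open.

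B lineage-like cells were 2.58% of kept cells in subcutaneous IRE 3 and averaged 0.887 ± 1.47% in that group (SD, n = 3). Cells of no named class were 12.97% of kept cells in subcutaneous sham 1.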
